A study of Rattus norvegicus with 36 samples.

How the data were processed

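The study sequenced RNA of iAM-1 cells, a line of conditionally immortalised atrial muscle cells from newborn rats. Per the labels' protocols, the cells proliferated in medium with 100 ng/ml doxycycline, were kept without it during differentiation, and received 100 ng/ml again during dedifferentiation. The labels give 36 samples in 9 groups of 4: days 0, 1, 2, 3 and 9 of differentiation (D0, D1, D2, D3, D9) and days 10, 11, 12 and 18, in dedifferentiation (D10, D11, D12, D18). Poly(A) RNA was selected and sequenced in pairs with a directional kit, per the labels' protocols. Nothing in the labels says whether the 4 samples of a day came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

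The authors deposited a table of CPM (counts scaled to 1e+06) and a table of TPM (transcripts scaled to 1e+06) with 1 column per sample. The genome build Rnor_6.0 and edgeR 3.26.8 are named in the submitters' processing notes, without the role of either. The aligner and the counter are not given in the sources used here. The deposited CPM values were checked on the file. They are a signal in which each column is whole reads times 1 step, and the columns sum to between 868992 and 1136457, so the authors' denominator was an effective library size and not the total of the listed genes. The planned design had called this table CPM, and the values are called CPM here with that meaning. All values of up to 20 reads were whole to within 0.1 read in every library (100% of them), and so were all of up to 1000 reads in the 1007 rows with more digits. The other 11941 rows are rounded to 4 digits or fewer, so their reads above about 1000 are approximate. The recovered reads came to between 29.7 and 86.2 M (M, 1e+06 reads) per library, with a median of 36.9 M, and 1 read was worth 0.0105 to 0.0361 CPM. The table lists 12948 rows, 12943 rat genes and 5 rows of the transferred constructs, and every listed row has at least 1 read in every library. Genes without reads in some library are therefore not analysed here. The deposited TPM table holds the 12943 rat genes and is in TPM per the file headers. Per-day means made by the authors were not used.

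Gene symbols and identifiers are those of the deposited table, and 11699 symbols were found in a rat gene table of the GRCr8 assembly, used for older symbols and not for coordinates. Symbols were missing or had turned into dates in 18 rows, which were tested but never named. Columns were matched to samples by the culture labels. 1 D1 column carries a culture label that matches none of the 4 D1 samples exactly. It was used as a D1 library without a number. Libraries of a day were compared in pairs for duplication by a chi-square per gene on recovered reads, and the pair that differed least within any day had a mean of 3.84, where sampling noise alone gives about 1, so no library was counted as a copy of another. No column was left without a day (0 of 36).

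The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(CPM + 0.5), over genes with at least 1 CPM in at least 4 libraries: 12487 rat genes and the 5 construct rows. All 36 libraries entered 1 fit with a mean per day, which leaves 27 residual degrees of freedom. Each gene got 1 estimate of spread over all days, although the days spread unequally. The median SD of a gene was log2 0.0728 at D1 and 0.252 at D12. An SE or p-value for 2 days therefore also carries the spread of the other days. Mb measured 32.45 ± 1.86 CPM at D9, but 66.4 ± 93.1 at D10 and 57.0 ± 96.7 at D12. All of these enter its SE between D9 and D0. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene counts as changed at an adjusted p under 0.05. The text prints adjusted p for the genes with the largest changes, for genes not called and for weak calls, and log2 fold change with SE for the others. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of genes with low values. All errors are SD over the 4 libraries of a day unless SE is written. The comparisons were D9 against D0, D18 against D9, D18 against D0, the 8 steps between consecutive sampled days, and the sum of the change from D0 to D3 and the change from D9 to D12, called the mirror contrast below, which is 0 where the first 3 days after doxycycline was given again undo the first 3 days without it. The pace of a phase is the median over genes of the share of the whole phase's change in log2(CPM + 0.5) reached at a day. It was computed over 1770 genes changed at least 2-fold in both phases in opposite directions. The design planned this median from the day means and no test. The values per library, the split into genes up and down at D9, and 9 two-sided exact permutation tests of 4 libraries against 4, adjusted over the 9, were added to that plan.

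The genes named were chosen by a rule fixed before the data were examined: in the 3 main comparisons, the 5 highest and 5 lowest log2 fold changes among changed genes with a mean of at least 10 CPM in the higher day and no overlap between the days; 26 anchor genes of the heart muscle cell and the cell cycle, of which Gja5 and Pecam1 are not analysed here; in each list, up to 4 changed members with the largest absolute log2 fold change and at least 10 CPM in the higher day; 3 highest and 3 lowest per step; and 5 and 5 in the mirror contrast, there without the overlap criterion. A few genes that the rule names are left out of the text. Names outside it are said to have been chosen after their values were seen. 32 gene lists, 7 of them cell type markers, were also fixed before the data were examined. Of these, 30 had at least 3 measured members and were tested with camera (inter-gene correlation preset at 0.01), with camera with an estimated correlation and with fry beside it. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. The correlation was estimated over all 36 libraries, also for comparisons without D10 to D12. The oxidative phosphorylation list had an SD of log2 0.066 at D9 and 0.059 at D18. Its SD was 0.28 at D10, 0.11 at D11 and 0.37 at D12. The list of mitochondrially encoded genes had no measured member, and the macrophage list had 2.

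Alternatives were pseudocounts of 0.1 and 2, no filter and a filter at a mean of 5 CPM, rescaling by median-of-ratios size factors, quantile normalization, the TPM table, the sample number as a block, only the 2 days compared in the fit, leaving out each library in turn, and, on the recovered reads, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. The count test by edgeR called 8919 genes in D9 against D0, 8238 in D18 against D9 and 6517 in D18 against D0. Library quality weights and a fit without D10, D11 and D12 were added after seeing the data. The fit was tested on simulated counts for D9 against D0 with 12104 genes, of which 200 were changed: limma called 50 of 50 genes at a log2 change of -2, 49 of 50 at -1, 49 of 50 at 1 and 50 of 50 at 2, with 12 calls among the unchanged genes. The simulated days all spread alike, so the fit was not tested under the unequal spread of the real days. Changed genes were drawn from those with at least 5 CPM at D0, and were a far smaller share than was called in the data. Reads of near-identical genes (Myh6 and Myh7, the actins, LOC100359539) can be split between copies by a counter, and their values are uncertain to that extent. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.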

Results

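The 36 libraries covered 9 days with 4 libraries each, and 12487 rat genes were tested. The first 2 principal components of the libraries held 56.5% and 20.9% of the variance. The median SD of a gene between the 4 libraries of a day, on the log2 scale, was 0.0853 at D0, 0.133 at D9, 0.165 at D10, 0.176 at D11, 0.252 at D12 and 0.122 at D18. Between D9 and D0, 8917 genes differed (4300 up, 4617 down), between D18 and D9 8254 (4195 up, 4059 down) and between D18 and D0 6492 (3590 up, 2902 down).

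The RNA of the transferred large T antigen followed doxycycline. It measured 2956 ± 158 CPM at D0, 682 ± 43.7 at D1, 335 ± 16.5 at D2, 36.0 ± 2.24 at D3 and 32.0 ± 3.00 at D9 (D9 against D0 log2 -6.51, SE 0.15, adjusted p = 1.0e-27). After doxycycline was given again it measured 417 ± 63.4 CPM at D10, 2130.2 ± 330.2 at D11, 2465 ± 967 at D12 and 4949.8 ± 415 at D18 (D18 against D9 log2 7.25, SE 0.15, adjusted p = 6.9e-29). The D18 level lay above D0 (log2 0.74, SE 0.15, adjusted p = 9.9e-05). The construct's repressor TetR-KRAB also fell and rose, with 699 ± 26.5 CPM at D0, 5.01 ± 0.654 at D9 (log2 -7.00, SE 0.17, adjusted p = 4.5e-27) and 1226 ± 30.3 at D18 (D18 against D9 log2 7.81, SE 0.17, adjusted p = 2.2e-28). The steps from D3 to D9 (log2 -0.17, SE 0.15, adjusted p = 0.381) and from D11 to D12 (log2 0.15, SE 0.15, adjusted p = 0.446) were not called for the T antigen. For TetR-KRAB the first of these was called (log2 -0.47, SE 0.17, adjusted p = 0.0235) and the second was not (log2 -0.19, SE 0.17, adjusted p = 0.393).

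**Figure D1:**
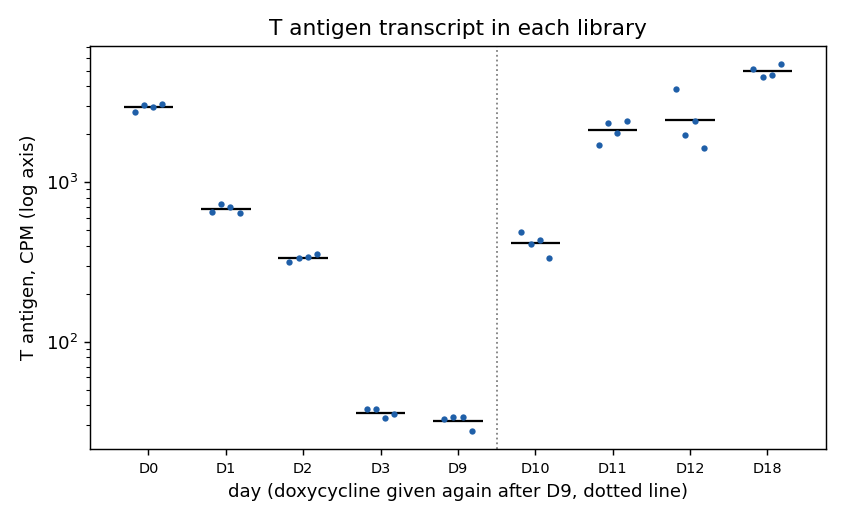
Large T antigen RNA in each library by day, with the day means as bars. The dotted line marks doxycycline given again after D9.

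At D9, genes of the contracting atrial cell stood above D0 and genes of the dividing cell lay below it. Myh6 rose from 789 ± 77.7 to 38219 ± 1358 CPM (log2 5.60, SE 0.28, adjusted p = 2.2e-18), and Top2a fell from 878 ± 42.6 to 1.50 ± 0.512 CPM (log2 -8.81, SE 0.20, adjusted p = 7.4e-28). Of the 8917 changed genes, 3184 changed at least 2-fold (1334 up, 1850 down). The share of changed genes that were up was 48.2% here and 27.1% in the TPM table. The median log2 change over all genes was -0.02 here and -0.35 in the TPM table. The 5 largest rises were those of Kcng2 (log2 5.99, SE 0.27, adjusted p = 1.4e-19), Myh6, Cox8b (log2 5.50, SE 0.36, adjusted p = 2.4e-15), Tnni3 (log2 5.50, SE 0.23, adjusted p = 2.4e-20) and Mb (log2 5.43, SE 0.65, adjusted p = 5.9e-09). Besides Top2a, the largest falls were those of Cenpf (log2 -8.09, SE 0.19, adjusted p = 2.3e-27), LOC100359539 (log2 -7.99, SE 0.17, adjusted p = 2.8e-28), Kif20a (log2 -7.90, SE 0.17, adjusted p = 2.2e-28) and Ccna2 (log2 -7.68, SE 0.21, adjusted p = 8.4e-26). Myh6 can share reads with Myh7, and LOC100359539 with a near-identical copy, so these values are uncertain to that extent.

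Of the anchor genes, the myosin light chain Myl7 rose from 178 ± 9.03 to 3449.5 ± 242 CPM (log2 4.27, SE 0.18). Actn2 (log2 3.28, SE 0.12), Ryr2 (log2 2.88, SE 0.15), Atp2a2 (log2 2.75, SE 0.16), Tnnt2 (log2 1.96, SE 0.12) and Kcnj3 (log2 1.20, SE 0.15) also rose. So did the regulators Ppargc1a (log2 2.69, SE 0.29), Tbx5 (log2 1.52, SE 0.10) and Nkx2-5 (log2 1.41, SE 0.09). Nppa rose (log2 1.82, SE 0.18) and so did Acta2 (log2 1.09, SE 0.17), which can share reads with other actins, but both turned negative under quantile normalization (log2 -0.28 for Nppa and -0.10 for Acta2). Ccnb1 (log2 -6.89, SE 0.16), Mki67 (log2 -5.26, SE 0.17), Mcm2 (log2 -3.50, SE 0.11) and Pcna (log2 -2.28, SE 0.13) fell, and so did Col1a1 (log2 -5.49, SE 0.20) and Vim (log2 -0.75, SE 0.18). Not called were Cdkn1a (log2 0.04, SE 0.10, adjusted p = 0.723), Gata4 (log2 0.06, SE 0.12, adjusted p = 0.652) and Cpt1b (log2 0.04, SE 0.27, adjusted p = 0.897), and in the TPM table Cdkn1a was called lower (log2 -0.29) and Gata4 too (log2 -0.27). There the median log2 change over all genes was also lower, at -0.35.

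Of the 30 lists tested between D9 and D0, 18 were called with the preset correlation and 7 with an estimated one. As many lists were called in 15 of the 35 splits of the 8 libraries, the real one included. Splits that mix the days unevenly keep part of the real difference, so this count cannot separate the calls from chance. Every measured DNA replication gene fell (46 down, median log2 -3.83, adjusted p = 2.1e-29, adjusted p = 0.0417 with an estimated correlation), for example Mcm5 (log2 -7.64, SE 0.18), Uhrf1 (log2 -7.34, SE 0.19) and Rrm2 (log2 -7.26, SE 0.17). Every mitosis gene fell as well (39 down, median log2 -6.38, adjusted p = 3.9e-33, adjusted p = 0.0417 with an estimated correlation). The fibroblast markers fell (9 down, median log2 -2.08, adjusted p = 2.1e-05, adjusted p = 0.0021 with an estimated correlation). Fbln1 (log2 -4.76, SE 0.17), Thy1 (log2 -3.83, SE 0.13) and S100a4 (log2 -2.89, SE 0.37) were among them. Interferon-stimulated genes fell (2 up, 18 down, 4 not called, median log2 -1.26, adjusted p = 2.6e-04, adjusted p = 0.0454 with an estimated correlation), with Cxcl10 (log2 -3.26, SE 0.19) and Isg15 (log2 -2.56, SE 0.14) among them. Skeletal muscle markers were called down (5 down, median log2 -1.67, adjusted p = 0.0282, adjusted p = 0.0669 with an estimated correlation), with Myh8 at log2 -2.31. The unfolded protein response was the last of the falling lists (2 up, 11 down, 5 not called, median log2 -0.79, adjusted p = 0.0247, adjusted p = 0.473 with an estimated correlation), with Asns at log2 -2.27.

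The sarcomere list was higher at D9 (23 up, 1 down, 1 not called, median log2 1.96, adjusted p = 1.1e-11, adjusted p = 0.0564 with an estimated correlation). Myh7 (log2 5.16, SE 0.29) and Tcap (log2 4.98, SE 0.29) followed Myh6 and Tnni3. Atrial genes rose (14 up, 1 down, median log2 1.75, adjusted p = 7.6e-07, adjusted p = 0.0204 with an estimated correlation), led by Myl7, Stard10 (log2 3.57, SE 0.19) and Kcnj5 (log2 2.72, SE 0.18). Ion channels rose (17 up, 2 not called, median log2 1.53, adjusted p = 1.1e-07, adjusted p = 0.0454 with an estimated correlation), with Kcnj11 (log2 3.49, SE 0.18) and Cacna1g (log2 3.13, SE 0.26). Cardiac transcription factors rose (13 up, 1 down, 4 not called, median log2 0.72, adjusted p = 7.6e-05, adjusted p = 0.0127 with an estimated correlation), with Smyd1 (log2 3.38, SE 0.16) and Mef2a (log2 1.81, SE 0.08). All oxidative phosphorylation genes rose (47 up, median log2 1.44, adjusted p = 1.2e-17, adjusted p = 0.129 with an estimated correlation), with Cox6c (log2 2.03, SE 0.11) behind Cox8b. All TCA cycle genes rose too (17 up, median log2 1.29, adjusted p = 3.3e-09, adjusted p = 0.129 with an estimated correlation), with Sdha at log2 1.97.

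Fatty acid oxidation was called up at D9 (24 up, 2 down, 2 not called, median log2 1.26, adjusted p = 6.0e-07, adjusted p = 0.216 with an estimated correlation), with Hadh at log2 2.26. Calcium handling was up (15 up, 5 down, 2 not called, median log2 1.22, adjusted p = 3.3e-04, adjusted p = 0.0763 with an estimated correlation), with Pln at log2 3.23. Autonomic receptors were up (11 up, 2 down, median log2 1.67, adjusted p = 2.9e-04, adjusted p = 0.0669 with an estimated correlation), with Adra1d at log2 4.05. Pacemaker genes were up (6 up, 1 not called, median log2 1.17, adjusted p = 0.00208, adjusted p = 0.0763 with an estimated correlation), with Hcn4 at log2 1.98. The intercalated disc was up (11 up, 1 down, 2 not called, median log2 0.46, adjusted p = 0.00175, adjusted p = 0.0564 with an estimated correlation), with Gja1 at log2 2.62. Lysosome and autophagy genes were up (16 up, 3 down, 6 not called, median log2 0.38, adjusted p = 0.0104, adjusted p = 0.216 with an estimated correlation), with Ctsd at log2 1.56.

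The 12 other lists were not called between D9 and D0. Ribosome biogenesis had no rising member (15 down, 9 not called, median log2 -0.45, adjusted p = 0.0531, with Nop58 -1.39). Epicardial markers had none either (5 down, 1 not called, median log2 -0.91, adjusted p = 0.0531, with Upk3b -2.40). Glycolysis (9 up, 2 down, 9 not called, median log2 0.18, adjusted p = 0.0531, with Pfkm 1.48) had 8 rising members when p was adjusted over the list alone, and all other lists had the same counts both ways. After rescaling by median-of-ratios size factors these 3 lists were called (adjusted p = 0.0496 each). With the sample number as a block camera called ribosome biogenesis (adjusted p = 0.0480). Ventricular genes had no falling member (2 up, 2 not called, median log2 0.46, adjusted p = 0.0868). TGF-beta and YAP targets (4 up, 11 down, 4 not called, median log2 -0.50, adjusted p = 0.219) and Schwann cell and neuron markers (1 up, 2 down, median log2 -2.10, adjusted p = 0.336) were split. So were smooth muscle markers (5 up, 2 down, 3 not called, median log2 0.28, adjusted p = 0.431, with Smtn -2.05 and Tagln 1.06, the latter log2 -0.18 under quantile normalization). Immediate early genes (8 up, 8 down, 2 not called, median log2 0.05, adjusted p = 0.646) held Egr1 (log2 3.97, SE 0.45) and Fos (log2 2.15, SE 0.48) beside falling Klf2 (log2 -2.74, SE 0.30). P53 targets were near 0 (9 up, 6 down, 8 not called, median log2 0.10, adjusted p = 0.534), with Sesn1 at log2 1.75. Cell cycle inhibitors (6 up, 8 down, 3 not called, median log2 -0.03, adjusted p = 0.556, with Rbl1 -4.01 and Cdkn1c 2.51) and cholesterol synthesis (2 up, 7 down, 10 not called, median log2 -0.02, adjusted p = 0.546) were near 0. For endothelial markers (1 up, 2 down, 2 not called, median log2 -0.40, adjusted p = 0.779) the mean was positive (0.02) because of Kdr (log2 3.79, SE 0.27). The medians of the endothelial, smooth muscle, glycolysis, immediate early, p53, cholesterol and cell cycle inhibitor lists changed sign under at least 1 other scaling. The 2 measured macrophage genes both measured lower at D9, Cd14 by log2 -2.08 and Csf1r by -1.36.

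When doxycycline was given again, cell division genes rose and most sarcomere and atrial genes fell by D18. Top2a rose from 1.50 ± 0.512 to 1572 ± 111 CPM (log2 9.64, SE 0.20, adjusted p = 6.9e-29), and Tcap fell from 30.9 ± 2.32 to 1.56 ± 0.623 CPM (log2 -3.98, SE 0.29, adjusted p = 7.4e-14). Of the 8254 changed genes, 2435 changed at least 2-fold (1502 up, 933 down). The share of changed genes that were up was 50.8%, against 40.2% after quantile normalization and 77.0% in the TPM table. The median log2 change over all genes was -0.00102, against -0.131 after quantile normalization and 0.341 in the TPM table. The largest rises besides Top2a were Cenpf (log2 8.57, SE 0.19, adjusted p = 3.9e-28), Cdca3 (log2 8.12, SE 0.22, adjusted p = 1.0e-25), Ccna2 (log2 8.12, SE 0.21, adjusted p = 1.4e-26) and Kif20a (log2 8.10, SE 0.17, adjusted p = 6.9e-29). Besides Tcap, the largest falls were Abi3bp (log2 -3.94, SE 0.49, adjusted p = 1.4e-08), Mb (log2 -3.90, SE 0.65, adjusted p = 3.4e-06), Angpt1 (log2 -3.72, SE 0.34, adjusted p = 1.7e-11) and Sema6a (log2 -3.43, SE 0.36, adjusted p = 4.4e-10).

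Among the anchors, Ccnb1 (log2 7.01, SE 0.16), Mki67 (log2 6.30, SE 0.17), Mcm2 (log2 4.17, SE 0.11) and Pcna (log2 3.03, SE 0.13) rose, and so did Cpt1b (log2 0.98, SE 0.27, adjusted p = 0.00185). Myh6 (log2 -2.89, SE 0.28), Actn2 (log2 -2.37, SE 0.12), Ryr2 (log2 -1.91, SE 0.15), Tnnt2 (log2 -1.75, SE 0.12) and Acta2 (log2 -1.37, SE 0.17) fell. Smaller falls were those of Nkx2-5 (log2 -0.89, SE 0.09), Myl7 (log2 -0.85, SE 0.18), Vim (log2 -0.85, SE 0.18), Tbx5 (log2 -0.75, SE 0.10) and Kcnj3 (log2 -0.63, SE 0.15). Cdkn1a fell (log2 -1.43, SE 0.10). Nppa (log2 -1.71, SE 0.18) and Atp2a2 (log2 -1.59, SE 0.16) fell, but under quantile normalization both were called higher (log2 0.55 and 0.36). Tnni3 fell (log2 -0.56, SE 0.23, adjusted p = 0.0341), a call lost when a library was left out. Col1a1 (log2 -0.23, SE 0.20, adjusted p = 0.33), Ppargc1a (log2 -0.34, SE 0.29, adjusted p = 0.319) and Gata4 (log2 -0.16, SE 0.12, adjusted p = 0.226) were not called.

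Between D18 and D9, 15 lists were called with the preset correlation (reached in 13 of 35 splits) and 2 with an estimated one. Those 2 were DNA replication (46 up, median log2 4.26, adjusted p = 4.3e-37, adjusted p = 0.0484 with an estimated correlation) and mitosis (39 up, median log2 6.81, adjusted p = 1.9e-39, adjusted p = 0.0484 with an estimated correlation). Uhrf1 (log2 8.02, SE 0.19) and Mcm5 (log2 7.89, SE 0.18) rose. The sarcomere list was lower at D18 (2 up, 21 down, 2 not called, median log2 -1.22, adjusted p = 4.9e-07, adjusted p = 0.191 with an estimated correlation), with Myh7 at log2 -2.64. Atrial genes were lower (13 down, 2 not called, median log2 -0.85, adjusted p = 4.2e-05, adjusted p = 0.0547 with an estimated correlation), with Sln (log2 -2.42, SE 0.26), Stard10 (log2 -2.27, SE 0.19) and Dkk3 (log2 -1.88, SE 0.16). Oxidative phosphorylation was lower (45 down, 2 not called, median log2 -0.96, adjusted p = 3.4e-13, adjusted p = 0.234 with an estimated correlation), with Cox8b (log2 -2.14, SE 0.36). The TCA cycle was lower (17 down, median log2 -1.01, adjusted p = 3.2e-08, adjusted p = 0.191 with an estimated correlation), with Sdha (log2 -1.38, SE 0.12). Fatty acid oxidation was lower (1 up, 25 down, 2 not called, median log2 -0.85, adjusted p = 2.7e-06, adjusted p = 0.268 with an estimated correlation), with Mlycd (log2 -1.83, SE 0.10). Calcium handling was lower (4 up, 15 down, 3 not called, median log2 -1.18, adjusted p = 9.9e-04, adjusted p = 0.171 with an estimated correlation), with Casq2 (log2 -2.21, SE 0.14) and, rising, Camk2b (log2 3.14, SE 0.29).

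Ion channels were lower at D18 (1 up, 14 down, 4 not called, median log2 -0.66, adjusted p = 0.00104, adjusted p = 0.209 with an estimated correlation), with Kcnd3 (log2 -2.39, SE 0.09). Autonomic receptors were lower (1 up, 11 down, 1 not called, median log2 -1.12, adjusted p = 7.1e-04, adjusted p = 0.151 with an estimated correlation), with Ednra (log2 -2.04, SE 0.19). Glycolysis was lower (14 down, 6 not called, median log2 -0.68, adjusted p = 1.8e-04, adjusted p = 0.191 with an estimated correlation), with Pfkm at log2 -1.37. Lysosome and autophagy genes were lower (2 up, 17 down, 6 not called, median log2 -0.67, adjusted p = 9.9e-04, adjusted p = 0.191 with an estimated correlation), with Ctsd at log2 -1.61. The intercalated disc was lower (2 up, 10 down, 2 not called, median log2 -0.50, adjusted p = 0.0124, adjusted p = 0.171 with an estimated correlation), with Dsp at log2 -1.23. Cardiac transcription factors were lower (1 up, 12 down, 5 not called, median log2 -0.37, adjusted p = 0.00641, adjusted p = 0.0771 with an estimated correlation), with Smyd1 at log2 -1.34. P53 targets were lower (5 up, 14 down, 4 not called, median log2 -0.84, adjusted p = 0.00749, adjusted p = 0.0547 with an estimated correlation), with Ccng1 at log2 -2.04 and Phlda3 at -1.84.

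The remaining 15 lists were not called between D18 and D9. Smooth muscle markers were mostly down (2 up, 7 down, 1 not called, median log2 -1.03, adjusted p = 0.0531), with Lmod1 at log2 -1.29. With the sample number as a block camera called them (adjusted p = 0.0423). Tagln fell (log2 -1.24, SE 0.18) but measured log2 0.12 under quantile normalization. Ribosome biogenesis had no falling gene (12 up, 12 not called, median log2 0.36, adjusted p = 0.0596), with Nop56 at log2 1.36. Interferon-stimulated genes were mixed (11 up, 2 down, 11 not called, median log2 0.35, adjusted p = 0.109), with Psmb9 at log2 1.56. Pacemaker genes were mixed too (1 up, 4 down, 2 not called, median log2 -0.47, adjusted p = 0.221), with Shox2 at log2 -1.26. For skeletal muscle markers the result was 3 up, 2 not called, median log2 0.55, adjusted p = 0.273. In the ventricular list (1 up, 3 down, median log2 -0.62, adjusted p = 0.283), Lbh measured log2 -0.22, and 0.14 in the TPM table. The median over all genes was log2 0.34 there. Fibroblast markers were mixed (3 up, 2 down, 4 not called, median log2 0.23, adjusted p = 0.58), with Fbln1 rising (log2 4.75, SE 0.17).

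Schwann cell and neuron markers gave 2 up, 1 not called, median log2 0.66, adjusted p = 0.333. Endothelial markers gave 1 down, 4 not called, median log2 -0.17, adjusted p = 0.61. Epicardial markers gave 2 up, 4 not called, median log2 0.39, adjusted p = 0.58. TGF-beta and YAP targets were split (4 up, 9 down, 6 not called, median log2 -0.29, adjusted p = 0.333), with Cyr61 at log2 -1.95. Cell cycle inhibitors were split (8 up, 5 down, 4 not called, median log2 0.31, adjusted p = 0.451), with Rbl1 at log2 4.32. So were cholesterol synthesis (8 up, 5 down, 6 not called, median log2 0.14, adjusted p = 0.58), with Dhcr7 at log2 1.79, and the unfolded protein response (7 up, 6 down, 5 not called, median log2 0.27, adjusted p = 0.58), with Asns at log2 2.83. Immediate early genes had a positive median although the test ranked them down (4 up, 5 down, 9 not called, median log2 0.06, adjusted p = 0.58), with Klf2 at log2 2.33. Adjusted over the list alone, 13 cardiac transcription factors and 5 pacemaker genes were down. The medians of TGF-beta and YAP targets, cholesterol synthesis and immediate early genes changed sign under another scaling.

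**Figure D2:**
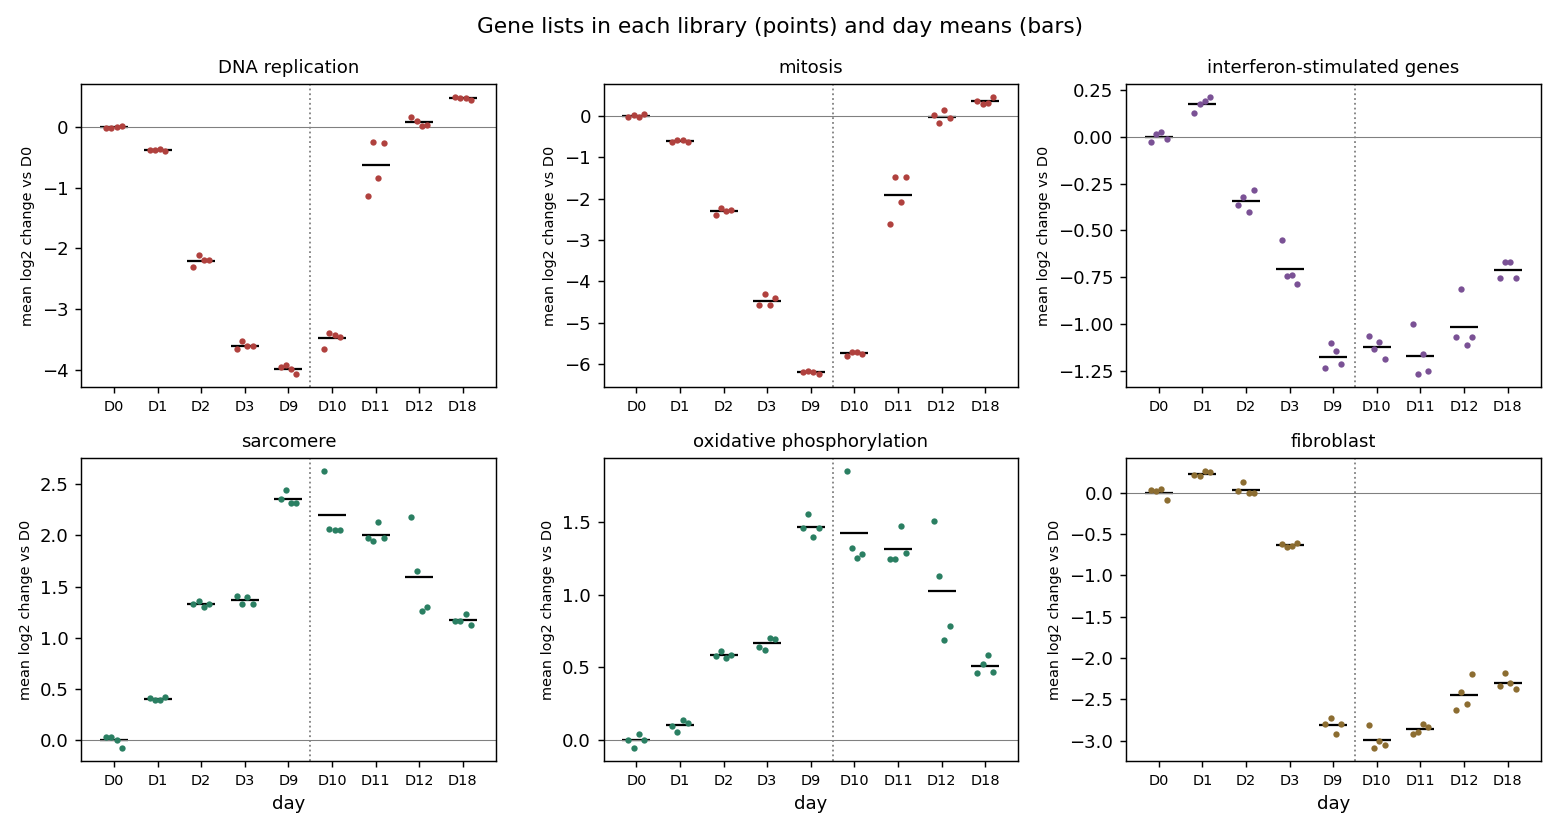
Mean log2 difference from D0 of gene lists by day, with points for libraries and bars for day means. Days are drawn as categories, and the dotted line marks doxycycline given again.

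Most of what changed by D9 moved back by D18. Of the 8917 genes changed between D9 and D0, 6274 (70.4%) changed the opposite way between D18 and D9, 3032 up then down and 3242 down then up, as Myh6 and Top2a did. The 2 comparisons share the D9 libraries, which alone makes their fold changes correlate negatively. The observed correlation over genes was -0.854, against a mean of -0.500 in 50 simulations of unchanged days (-0.516 to -0.479), in which 0 genes were called. All fold changes of unchanged days are noise, so their correlation does not show how much of the observed one comes from sharing D9. The observed covariance was -1.19, against a mean of -0.0119 in the simulations. With the D9 libraries split 2 and 2 between the comparisons, the share was 65.3% to 67.5% and the correlation -0.844 to -0.840. 409 genes changed the same way in both phases (136 up, 273 down). Of the 3184 genes that changed at least 2-fold by D9, 2686 (84.4%) reversed, 1707 still differed from D0 on the same side at D18, 740 of them at least 2-fold, and 425 had crossed to the other side.

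**Figure D3:**
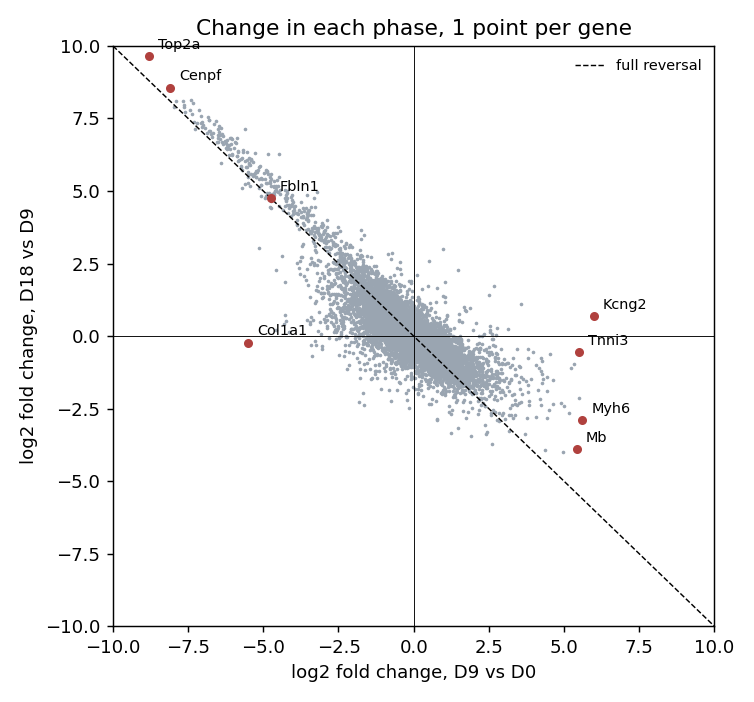
Log2 fold change of each gene between D9 and D0 and between D18 and D9. The comparisons share the D9 libraries.

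At D18 the cells did not match D0. Tnni3 measured 4.93 ± 0.0299 CPM at D0 and 166 ± 12.9 at D18 (log2 4.94, SE 0.23, adjusted p = 1.3e-17), and Col1a1 246 ± 9.09 and 4.25 ± 1.01 (log2 -5.72, SE 0.20, adjusted p = 1.4e-20). Of the 6492 changed genes, 1127 differed at least 2-fold (460 up, 667 down). The highest were Kcng2 (log2 6.67, SE 0.27, adjusted p = 2.0e-19), Tnni3, Murc (log2 4.70, SE 0.36, adjusted p = 1.7e-12), Sh3kbp1 (log2 4.40, SE 0.30, adjusted p = 7.5e-14) and Sorcs2 (log2 4.39, SE 0.29, adjusted p = 4.3e-14). The lowest besides Col1a1 were Igf1 (log2 -4.39, SE 0.45, adjusted p = 9.1e-10), Lox (log2 -4.10, SE 0.23, adjusted p = 5.9e-16), Col3a1 (log2 -4.08, SE 0.21, adjusted p = 1.5e-16) and Wisp2 (log2 -4.02, SE 0.30, adjusted p = 5.4e-13). Among the anchors Myl7 (log2 3.42, SE 0.18), Myh6 (log2 2.71, SE 0.28), Ppargc1a (log2 2.36, SE 0.29), Atp2a2 (log2 1.15, SE 0.16) and Cpt1b (log2 1.02, SE 0.27, adjusted p = 0.00188) were higher.

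Mki67 (log2 1.04, SE 0.17), Top2a (log2 0.84, SE 0.20), Pcna (log2 0.75, SE 0.13) and Mcm2 (log2 0.66, SE 0.11) lay above D0 at D18. So did Ryr2 (log2 0.96, SE 0.15), Actn2 (log2 0.91, SE 0.12), Tbx5 (log2 0.77, SE 0.10), Kcnj3 (log2 0.57, SE 0.15, adjusted p = 0.00246) and Nkx2-5 (log2 0.52, SE 0.09). Vim (log2 -1.60, SE 0.18) and Cdkn1a (log2 -1.39, SE 0.10) lay below. Nppa (log2 0.11, SE 0.18, adjusted p = 0.623), Tnnt2 (log2 0.21, SE 0.12, adjusted p = 0.164), Acta2 (log2 -0.28, SE 0.17, adjusted p = 0.169), Ccnb1 (log2 0.12, SE 0.16, adjusted p = 0.551) and Gata4 (log2 -0.10, SE 0.12, adjusted p = 0.486) were not called.

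Between D18 and D0, 18 lists were called with the preset correlation (reached in 3 of 35 splits) and 2 with an estimated one. Those 2 were the fibroblast markers (8 down, 1 not called, median log2 -1.85, adjusted p = 6.8e-08, adjusted p = 3.6e-05 with an estimated correlation) and the p53 targets (4 up, 16 down, 3 not called, median log2 -0.68, adjusted p = 4.7e-04, adjusted p = 0.00819 with an estimated correlation). Ddr2 (log2 -2.13, SE 0.19), Plk2 (log2 -1.18, SE 0.41, adjusted p = 0.0163) and Mdm2 (log2 -0.98, SE 0.13) were among them. Sarcomere genes were higher (18 up, 1 down, 6 not called, median log2 0.93, adjusted p = 2.0e-07, adjusted p = 0.19 with an estimated correlation), with Myh7 (log2 2.52, SE 0.29). Ion channels were higher (14 up, 1 down, 4 not called, median log2 0.78, adjusted p = 7.8e-05, adjusted p = 0.175 with an estimated correlation), with Abcc8 (log2 2.67, SE 0.17) and Hcn4 (log2 2.19, SE 0.36). Oxidative phosphorylation was higher (35 up, 12 not called, median log2 0.43, adjusted p = 2.5e-06, adjusted p = 0.45 with an estimated correlation), with Cox7c (log2 0.82, SE 0.13). DNA replication was higher (31 up, 15 not called, median log2 0.46, adjusted p = 2.7e-05, adjusted p = 0.447 with an estimated correlation), with E2f8 (log2 1.50, SE 0.25). Mitosis was higher (14 up, 25 not called, median log2 0.32, adjusted p = 0.00907, adjusted p = 0.626 with an estimated correlation), with Foxm1 (log2 0.83, SE 0.16).

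Atrial genes were called up at D18 (8 up, 2 down, 5 not called, median log2 0.57, adjusted p = 0.00887, adjusted p = 0.199 with an estimated correlation), with Mybphl at log2 1.34. Pacemaker genes were up (5 up, 2 not called, median log2 1.27, adjusted p = 0.00907, adjusted p = 0.193 with an estimated correlation). Cardiac transcription factors were up (11 up, 1 down, 6 not called, median log2 0.41, adjusted p = 0.00845, adjusted p = 0.0856 with an estimated correlation), with Smyd1 at log2 2.04. The TCA cycle was up (10 up, 7 not called, median log2 0.26, adjusted p = 0.0153, adjusted p = 0.564 with an estimated correlation), with Sdha at log2 0.59. Interferon-stimulated genes were down (1 up, 16 down, 7 not called, median log2 -0.43, adjusted p = 7.8e-05, adjusted p = 0.0512 with an estimated correlation), with Isg15 at log2 -2.36. TGF-beta and YAP targets were down (1 up, 12 down, 6 not called, median log2 -0.64, adjusted p = 6.5e-04, adjusted p = 0.428 with an estimated correlation). The unfolded protein response was down (4 up, 11 down, 3 not called, median log2 -0.53, adjusted p = 0.00403, adjusted p = 0.428 with an estimated correlation), with Hspa5 at log2 -1.37. Epicardial markers were down (3 down, 3 not called, median log2 -0.73, adjusted p = 0.00845, adjusted p = 0.0856 with an estimated correlation), with Upk3b at log2 -2.06. Glycolysis was down (10 down, 10 not called, median log2 -0.25, adjusted p = 0.00907, adjusted p = 0.428 with an estimated correlation), with Slc2a1 at log2 -1.20.

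Smooth muscle markers were down at D18 (1 up, 5 down, 4 not called, median log2 -0.52, adjusted p = 0.0286, adjusted p = 0.294 with an estimated correlation), with Cald1 at log2 -1.17. Skeletal muscle markers were the last called list (4 down, 1 not called, median log2 -0.75, adjusted p = 0.0404, adjusted p = 0.165 with an estimated correlation), with Myh2 at log2 -1.68. Not called were autonomic receptors (7 up, 3 down, 3 not called, median log2 0.45, adjusted p = 0.062) and fatty acid oxidation (14 up, 4 down, 10 not called, median log2 0.37, adjusted p = 0.0841). Calcium handling (8 up, 2 down, 12 not called, median log2 0.18, adjusted p = 0.105) and ventricular genes (3 up, 1 down, median log2 0.88, adjusted p = 0.222) were not called. The intercalated disc was not called (6 up, 5 down, 3 not called, median log2 0.14, adjusted p = 0.277), with Gja1 at log2 2.53. Neither were endothelial (1 up, 2 down, 2 not called, median log2 -0.42, adjusted p = 0.442) and Schwann cell and neuron markers (1 up, 1 down, 1 not called, median log2 -0.20, adjusted p = 0.575). Lysosome and autophagy (4 up, 5 down, 16 not called, median log2 -0.06, adjusted p = 0.492) and ribosome biogenesis (2 up, 22 not called, median log2 -0.06, adjusted p = 0.716) lay near 0.

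The other 3 lists had signs that differed between measures. Cell cycle inhibitors (6 up, 4 down, 7 not called, median log2 0.24, adjusted p = 1), with Btg1 at log2 1.37, were ranked down by the test. Immediate early genes (5 up, 4 down, 9 not called, median log2 -0.39, adjusted p = 0.7), with Egr1 at log2 3.42, had a mean of 0.08. Cholesterol synthesis (3 up, 5 down, 11 not called, median log2 -0.03, adjusted p = 0.725) had a mean of 0.01. The 2 macrophage genes stayed low, Cd14 at log2 -2.28 and Csf1r at -1.23. Adjusted over the list alone, 32 DNA replication genes, 37 oxidative phosphorylation genes, 15 ion channels, 7 cell cycle inhibitors and 2 TGF-beta and YAP targets were up. On that count 4 epicardial genes and 2 cardiac transcription factors were down, and interferon-stimulated genes had 2 up and 17 down.

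On the first day of differentiation most p53 targets rose and most mitosis genes fell. At D1, 1532 genes differed from D0 (988 up, 544 down), 84 of them at least 2-fold, with 64.5% up, against 51.7% after quantile normalization and 37.0% in the TPM table. The D1 count was 5262 with only the 2 days in the fit, 5560 with library quality weights and 3975 in a fit without D10 to D12. AABR07053509.2 (log2 2.20, SE 0.20), Plcd4 (log2 2.12, SE 0.23) and Ltk (log2 1.74, SE 0.26) rose most, and Ldhb (log2 -1.81, SE 0.17), Glcci1 (log2 -1.18, SE 0.13) and Arhgef39 (log2 -1.04, SE 0.19) fell most. 17 of 23 p53 targets rose and 26 of 39 mitosis genes fell. From D1 to D2, 5188 genes changed (2693 up, 2495 down; 51.9% up, 20.2% in the TPM table), against 7924 with only the 2 days in the fit and 8124 with library quality weights. The largest rises were those of Corin (log2 2.68, SE 0.16), Rab3b (log2 2.42, SE 0.24) and Tnni3 (log2 2.35, SE 0.23). The largest falls were those of Uhrf1 (log2 -2.98, SE 0.19), Cdc6 (log2 -2.84, SE 0.16) and Tk1 (log2 -2.81, SE 0.19). All 46 DNA replication genes fell in that step and 40 oxidative phosphorylation genes rose.

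From D2 to D3, 1574 genes changed (365 up, 1209 down; 23.2% up, 43.5% after quantile normalization), against 4190 with only the 2 days, 4384 with weights and 3720 without D10 to D12. Sh3kbp1 (log2 1.19, SE 0.30, adjusted p = 0.00549), Slc16a12 (log2 1.13, SE 0.23) and Ptgr1 (log2 1.12, SE 0.13) rose, and Mcm5 (log2 -3.15, SE 0.18), Ccna2 (log2 -3.11, SE 0.21) and Cit (log2 -3.04, SE 0.21) fell. From D3 to D9, 5418 genes changed (2294 up, 3124 down; 42.3% up, 27.6% in the TPM table). Mb (log2 4.42, SE 0.65), Txlnb (log2 3.76, SE 0.37) and Kcng2 (log2 3.61, SE 0.27) rose most, and Fbln1 (log2 -4.28, SE 0.17), Col1a1 (log2 -3.82, SE 0.20) and Cxcl10 (log2 -3.51, SE 0.19) fell most.

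After doxycycline was given again, some DNA replication genes, such as Mcm5, and some mitosis genes were among the first to rise. From D9 to D10, 453 genes changed (295 up, 158 down; 65.1% up, 85.9% in the TPM table). With only the 2 days in the fit the balance turned (51 up, 63 down; 44.7% up). The count was 114 in that fit, 283 after quantile normalization, 703 with DESeq2, 2057 with library quality weights and 229 without D9 replicate 2. Mcm5 (log2 2.92, SE 0.18), Podxl (log2 1.60, SE 0.39, adjusted p = 0.015) and Inha (log2 1.43, SE 0.09) rose most. The largest falls were those of Egr1 (log2 -2.86, SE 0.45), Cyr61 (log2 -2.69, SE 0.37) and Fos (log2 -2.10, SE 0.48, adjusted p = 0.00939). 18 of 46 DNA replication and 15 of 39 mitosis genes had risen, and 28 and 24 were not called. From D10 to D11, 3187 genes changed (1958 up, 1229 down), against 1892 with only the 2 days and 5210 with weights. All 46 DNA replication and 39 mitosis genes rose. Top2a (log2 6.06, SE 0.20), LOC100359539 (log2 5.87, SE 0.17) and Fam111a (log2 5.84, SE 0.20) rose most, and Ddit4 (log2 -1.53, SE 0.24), Sema7a (log2 -1.27, SE 0.38, adjusted p = 0.0123) and Pfkfb3 (log2 -1.27, SE 0.12) fell most. Of the genes changed in this step 61.4% were up, against 48.4% after rescaling by median-of-ratios size factors, 43.7% after quantile normalization and 48.4% with DESeq2.

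From D11 to D12, 4995 genes changed (2337 up, 2658 down; 46.8% up, 66.6% in the TPM table), against 1155 with only the 2 days in the fit (60.7% up). Kif20a (log2 2.58, SE 0.17), Pif1 (log2 2.46, SE 0.18) and Cenpf (log2 2.42, SE 0.19) rose, and Slc16a12 (log2 -2.72, SE 0.23), Mest (log2 -2.07, SE 0.32) and Atp6ap1l (log2 -1.92, SE 0.22) fell. 14 of 18 immediate early genes rose and 27 oxidative phosphorylation genes fell. Not every D12 library moved this way. The immediate early list measured -0.51 ± 0.14 log2 against D0 at D11 and -0.64, 0.05, 1.97 and 1.90 in replicates 1 to 4 of D12. Oxidative phosphorylation measured 1.31 ± 0.11 and 1.51, 1.13, 0.69 and 0.78. From D12 to D18, 6111 genes changed (3177 up, 2934 down; 52.0% up, 74.7% in the TPM table), against 3576 with only the 2 days in the fit. Tenm4 (log2 2.97, SE 0.25), Aqp1 (log2 2.86, SE 0.36) and Atp1b2 (log2 2.72, SE 0.15) rose most, and Tiam2 (log2 -3.37, SE 0.36), Mb (log2 -3.10, SE 0.65) and Wisp2 (log2 -2.99, SE 0.30) fell most. Mb measured 57.0 ± 96.7 CPM at D12 and 1.71 ± 0.229 at D18, so its D12 libraries lay far apart.

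By the median SD of a gene, the 4 libraries of D12 differed from each other more than those of any other day. In replicates 1 to 4, ribosome biogenesis measured -0.40, -0.21, 0.78 and 0.97 log2 against D0, TGF-beta and YAP targets -1.26, -0.69, 0.19 and 0.10 and sarcomere 2.18, 1.65, 1.26 and 1.30. The mitosis list measured 0.03, -0.17, 0.14 and -0.06. Fos measured 6.83, 11.4, 114 and 125 CPM and Myh6 24449, 11017, 4599 and 4750 CPM, both picked for this after their values were seen. The mitosis and DNA replication lists spread more at D11 (SD log2 0.540 and 0.444) than at D12 (0.134 and 0.0691).

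**Figure D4:**
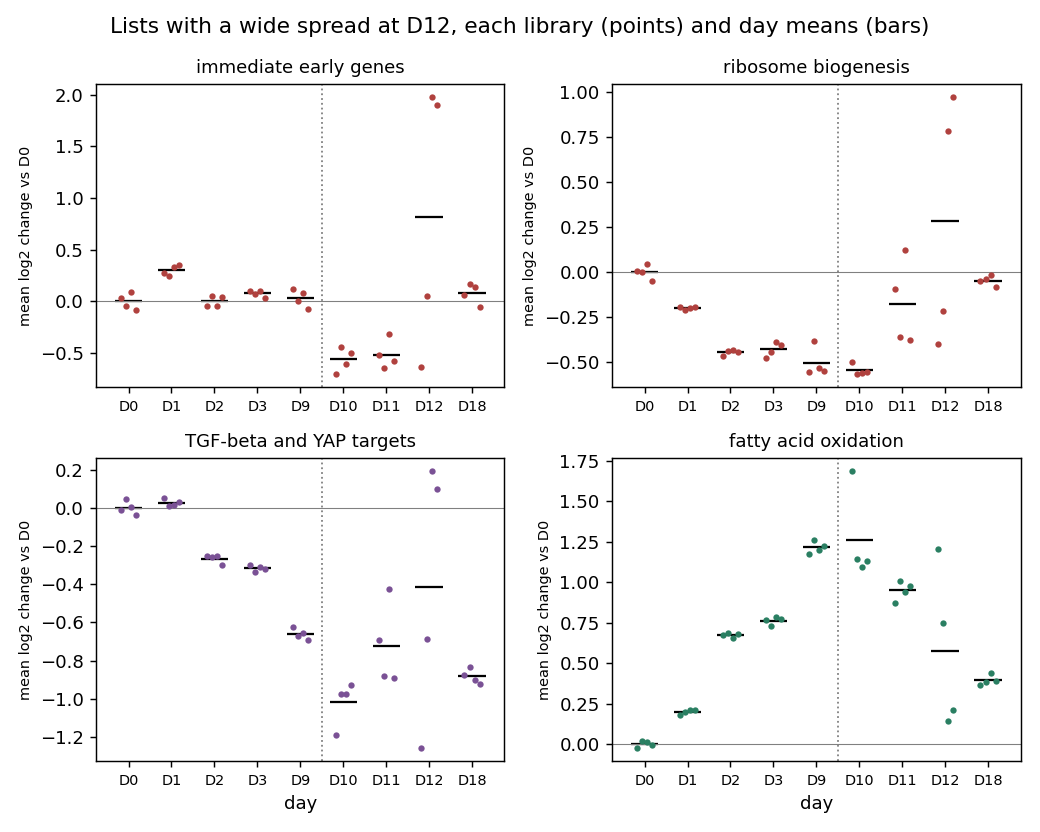
Mean log2 difference from D0 of gene lists with a wide spread at D12, by day, with points for libraries and bars for day means. The lists were picked for that spread.

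On the log2 scale, dedifferentiation began more slowly than differentiation. The order can differ in CPM, in which the pace was not computed. Myh6 measured 789 CPM at D0, 6573 at D2 and 38219 at D9, then 25702 at D11 and 5162 at D18. On the log2 scale Myh6 had covered more of its change at D2 than at D11. In CPM the order was reversed, with more of the change covered at D11. Over the 1770 genes that moved at least 2-fold in both phases, 13.7 ± 0.394% of the whole change was reached at D1, 53.7 ± 1.24% at D2 and 77.2 ± 1.31% at D3, against 5.18 ± 1.26% at D10, 40.6 ± 3.64% at D11 and 81.0 ± 7.01% at D12 (n = 4 libraries each). Exact permutation tests gave p = 0.0286 after 1 and 2 days, the smallest possible with 4 against 4 (adjusted p = 0.0429 over 9 tests), and p = 0.371 after 3 days, where replicates 1 to 4 of D12 had reached 73.5%, 76.6%, 86.7% and 87.3%. All shares were taken against the same day means of D0, D9 and D18. An error in these means moves all libraries of a day together, and the permutation tests do not cover it. The 632 genes up at D9, such as Myh6, had fallen back by 2.39 ± 5.41% at D10, 26.4 ± 6.57% at D11 and 70.0 ± 26.0% at D12, and had risen by 18.8%, 58.0% and 66.2% at D1, D2 and D3 (exact permutation p = 0.0286, 0.0286 and 0.714). The 1138 genes down at D9, such as Top2a, had returned by 6.05%, 52.0% and 85.4%, against falls of 11.7%, 51.7% and 81.3% (exact permutation p = 0.0286, 0.971 and 0.0286). In the first set, replicates 1 to 4 of D10 had reached -5.60%, 4.14%, 6.43% and 4.57%, and those of D12 41.9%, 53.9%, 90.6% and 93.6%.

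**Figure D5:**
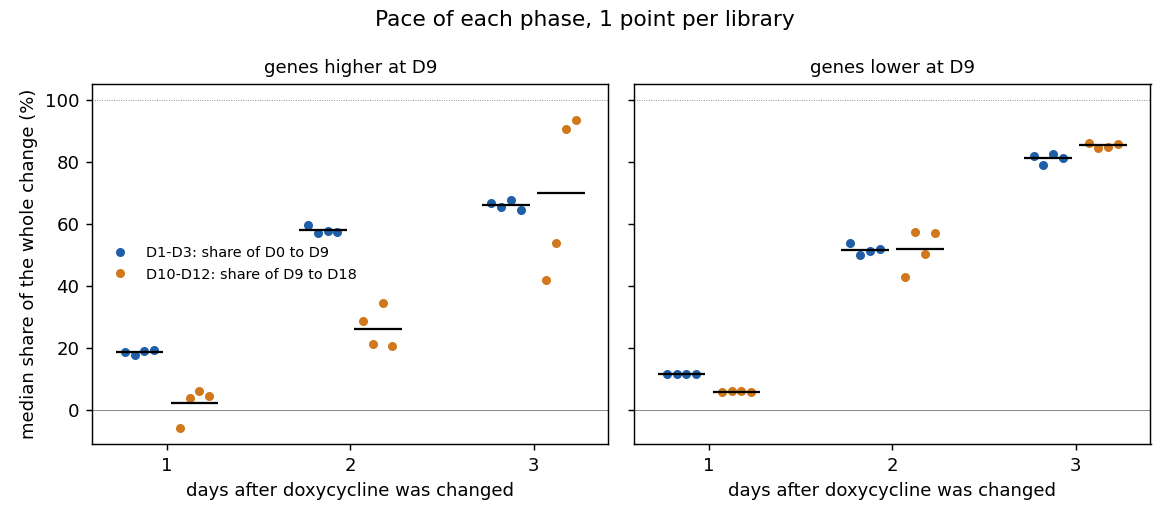
Share of the whole log2 change of each phase reached after 1, 2 and 3 days, per library. The genes moved at least 2-fold in both phases in opposite directions.

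In the mirror contrast, 2928 genes departed from 0 (1801 up, 1127 down), 709 of them at least 2-fold. With library quality weights it called 6110. The main count was reached in 9 of 100 drawn assignments of the libraries. The highest were Tiam2 (log2 3.87, SE 0.51, adjusted p = 1.1e-06), Top2a (log2 3.49, SE 0.28, adjusted p = 7.6e-11), Cenpf (log2 3.30, SE 0.27, adjusted p = 1.1e-10), Tnni3 (log2 3.19, SE 0.33, adjusted p = 1.1e-08) and Arhgap11a (log2 3.11, SE 0.20, adjusted p = 5.1e-13). The lowest were LOC100911486 (log2 -3.07, SE 0.30, adjusted p = 3.0e-09), Erbb3 (log2 -2.50, SE 0.26, adjusted p = 1.5e-08), Bst2 (log2 -2.27, SE 0.18, adjusted p = 7.6e-11), Cilp2 (log2 -2.26, SE 0.41, adjusted p = 1.2e-04) and Upk3b (log2 -2.22, SE 0.17, adjusted p = 2.6e-11). 37 of 39 mitosis genes were above 0, so their rise from D9 to D12 was larger than their fall from D0 to D3. All 39 fell further from D3 to D9, and the list measured -0.01 ± 0.13 log2 against D0 at D12. Of the genes called, 61.5% were above 0, against 49.0% after rescaling by median-of-ratios size factors, 46.7% after quantile normalization and 49.8% in the TPM table.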

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

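The tests of the D12 libraries and of the D18 state were chosen only after those results were seen, and the counts over other splits of the libraries were planned before. A single library stood apart from the 3 others of its day in 20 of 246 groups tested, where chance alone gives about 1 in 20, and the 8 gene lists among them were picked after their values per library were seen. D9 replicate 2 held more Atp2a2 (23180 CPM), Tnni3 (340 CPM), Tnnt2 (11590 CPM) and Wisp2 (32.6 CPM), less Tbx5 (584.8 CPM), a CPM total of 1132 k and a ribosome biogenesis mean of log2 -0.3851. D10 replicate 1 had a CPM total of 1136 k, 15.61% of it in its 10 highest genes and 3.038% in Nppa, with list means of log2 2.624 for sarcomere, 1.845 for oxidative phosphorylation and 1.685 for fatty acid oxidation. D11 replicate 3 had a CPM total of 1074 k and an oxidative phosphorylation mean of log2 1.471. Gata4 was low in D0 replicate 4 (366 CPM) and D18 replicate 4 (324 CPM), Kif20a in D9 replicate 1 (0.314 CPM), the T antigen in D9 replicate 4 (27.6 CPM), and D3 replicate 1 had the fewest reads of its day (30.44 M).

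The 2 phases were compared by tests of the difference itself, the mirror contrast and the permutation tests of pace. The mirror count was reached in 9 of 100 drawn assignments, and its balance depended on the scaling. Of the genes called, 61.5% lay above 0, against 49.0% after median-of-ratios scaling and 46.7% after quantile normalization. The mirror contrast called 2928 genes, among them Tiam2 (log2 3.87), Top2a (3.49), Cenpf (3.30), Tnni3 (3.19), Arhgap11a (3.11), LOC100911486 (-3.07), Erbb3 (-2.50), Bst2 (-2.27), Cilp2 (-2.26) and Upk3b (-2.22). In percentage points of the whole log2 change, dedifferentiation differed from differentiation by -8.52 after 1 day and -13.1 after 2 days over all genes of the set. The differences were -16.4 and -31.6 after 1 and 2 days for genes up at D9, and -5.68 after 1 day and 4.10 after 3 days for genes down at D9.

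Each count of changed genes was the highest of all 35 splits of its 8 libraries, so 1 of 35 reached it. The highest other split gave 2724 genes for D9 against D0, 2517 for D18 against D9, 101 for D18 against D0, 0 for D1 against D0, 2 for D2 against D1, 0 for D3 against D2, 44 for D9 against D3, 12 for D10 against D9, 1804 for D11 against D10, 4297 for D12 against D11 and 3143 for D18 against D12. For the reversal, 1 of 100 assignments, the real one, reached 6274 genes, and the highest other gave 2585. For called lists, 15 of 35 splits reached the 18 of D9 against D0 (highest 20). 13 of 35 reached the 15 of D18 against D9 (highest 17), and 3 of 35 the 18 of D18 against D0 (highest 18). Splits that mix the 2 days unevenly keep part of the real difference, and camera ranks genes against each other. These counts therefore cannot tell whether the list calls arise from chance. The count of the mirror contrast was reached in 9 of 100 assignments (highest 7004). There, reassignment by construction can turn opposite changes into changes that add up.

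The spread among the D12 libraries was weighed against 4 explanations. Depth as the sole cause was excluded, since along the order of reads the immediate early list both rose and dropped by at least log2 1.85. Different points along 1 course stay open: the highest D12 library lay log2 1.67 (immediate early), 0.968 (ribosome biogenesis) and -0.178 (sarcomere) from the highest mean of the other days, but these lists were picked for their spread and a peak between sampled days would not be seen. RNA of other cell types stays open too, because the marker lists (highest log2 -0.0671 against D0) are expressed at D0 and lack genes without reads in some library. A D11 library carrying a D12 label was excluded, since the mitosis list of the lowest D12 library lay log2 1.31 above the highest D11 library. The labels give the 4 libraries no difference, so no biological explanation from the design was tested. The construct also differed among them. The T antigen ranged from 1637 to 3830 CPM at D12 (1705 to 2420 at D11) and TetR-KRAB from 340 to 929 (520 to 646 at D11). Whether this goes with the spread of the lists was not tested.

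The distance of D18 from D0 was weighed in the same way. Scaling by 1 factor per library was excluded as the sole cause, as it moves all genes alike, while 460 genes lay at least 2-fold above D0 and 667 below. A remaining share of cells in the D9 state was excluded as the sole cause, as 45 members of the DNA replication and mitosis lists lay above D0 and none below. Fewer fibroblast-like cells stay open. The fibroblast markers lay up to log2 5.71 apart, from Col1a1 (log2 -5.72) to Fbln1 (log2 -0.0085). A marker that other cells also make would fall less, so this gap cannot decide. Time in culture stays open, because no library kept in doxycycline for 18 days was analysed here. The level of the construct stays open as well. The T antigen (log2 0.74, SE 0.15) and TetR-KRAB (log2 0.81, SE 0.17) lay above D0 at D18. Whether this goes with the distance of D18 from D0 was not tested.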

How the results depend on the processing

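All counts below are of changed genes unless said otherwise, and the cause of a moved count, share or direction was not tested. Fitting only the 2 days compared gave 5262 for D1 against D0 (1532 in the report), 7924 for D2 against D1 (5188), 4190 for D3 against D2 (1574), 114 for D10 against D9 (453), 1892 for D11 against D10 (3187), 1155 for D12 against D11 (4995) and 3576 for D18 against D12 (6111). Here the fit's own construction, a spread from 2 days in place of 9, is the change. Library quality weights, chosen after seeing the data, gave 5560, 8124 and 4384 for the first 3 steps, 2057 for D10 against D9, 5210 for D11 against D10, 6110 for the mirror contrast (2928) and a reversed share of 73.14% (70.4%). A fit without D10 to D12, also chosen after seeing the data, gave 3975 for D1 against D0, 3720 for D3 against D2 and 73.54%. D10 against D9 gave 283 with quantile normalization and 703 with DESeq2. The reversed share was 71.543% at a mean of 5 CPM and 73.895% in the TPM table.

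The share of the whole change reached at D1, from the day means, was 14.0% and gave 13.03% and 14.447% with pseudocounts 0.1 and 2, 14.403% with median-of-ratios scaling, 14.938% with TPM, 12.845% with edgeR and 13.371% with DESeq2. At D2 (53.8%) the values were 51.634%, 56.405%, 55.463% (quantile), 58.224% (TPM), 50.634% (edgeR) and 51.675% (DESeq2). At D3 (78.1%) they were 75.091%, 80.614%, 73.933% (edgeR) and 73.78% (DESeq2), and at D10 (5.33%) 6.69% with TPM. With an estimated correlation 7, 2 and 2 lists were called for D9 against D0, D18 against D9 and D18 against D0, and fry called 28 and 25 for the first 2.

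Reversed under quantile normalization were Nppa (-0.275), Acta2 (-0.103) and Tagln (-0.183) between D9 and D0, and Atp2a2 (0.359), Nppa (0.549) and Tagln (0.12) between D18 and D9. In the TPM table, Cdkn1a (-0.294) and Gata4 (-0.274) between D9 and D0 and Lbh (0.143) between D18 and D9 reversed. They moved with the median log2 change over all genes. Between D9 and D0 this median was -0.0242 in the main fit and -0.346 in the TPM table. Between D18 and D9 it was -0.00102 and 0.341. Leaving out 1 library gave 229 to 426 for D10 against D9, 68.163% to 71.581% for the reversed share and 76.748% to 78.116% for D3. In the 3 main comparisons it ended 20 calls in 6 of 362 named results (Fos, Junb and Dkc1 between D18 and D0; Lbh, Tnni3 and Upk3b between D18 and D9). Pseudocounts, no filter, median-of-ratios scaling and edgeR kept all 420 results of named genes, DESeq2 the 416 and the filter at 5 CPM the 415 for which they gave a value. Besides the reversals, 7 of these lost their call under quantile normalization, 5 in the TPM table and 1 with only the 2 days in the fit. Between 93.3% and 99.3% of the calls of a comparison were shared with edgeR.

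The labels give the libraries replicate numbers without saying that these pair them, and they were not treated as pairs, since only 21 of 136 same-number pairs had a correlation of deviations above 0.1. By that measure 18 of 35 libraries were closest to their own number, where chance gives about 1 in 4, a hint of pairing from the data and not from the design. The replicate block gave 1002 for D1 against D0. That fit also leaves out the D1 library without a number, which alone gave 1080. The block added 2 list calls, ribosome biogenesis for D9 against D0 (adjusted p = 0.0480) and smooth muscle markers for D18 against D9 (adjusted p = 0.0423), and Junb between D18 and D0 lost its call. It changed no other call of a named gene or list.

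Median-of-ratios scaling added 3 list calls for D9 against D0, epicardial markers, glycolysis and ribosome biogenesis (adjusted p = 0.0496 each).

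Depth limits the low values: 1 read was worth up to 0.0361 CPM, and genes without a read in some library were not analysed here.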

Other observations

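Some genes moved the same way in both phases instead of returning, and those named here were picked after their values were seen. 26 genes changed at least 2-fold in the same direction in both phases (8 up, 18 down). Sorcs2 measured 1.38 ± 0.143 CPM at D0, 11.5 ± 0.814 at D9 and 38.7 ± 1.68 at D18. Cdh6 measured 0.226 ± 0.0986, 3.65 ± 0.811 and 10.5 ± 0.695. Among those that fell, Ccnd1 measured 412 ± 6.85, 168 ± 7.89 and 72.3 ± 7.06, Tnc 109 ± 5.19, 33.5 ± 1.34 and 8.45 ± 1.91, and Col12a1 835 ± 38.7, 354 ± 30.4 and 153 ± 12.9.

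Single genes in the libraries of D10 to D12, also picked after their values were seen, are given as values of replicates 1 to 4 in CPM. At D12 Egr1 measured 16.7, 66.4, 232 and 229 and Dusp4 8.04, 10.3, 58.0 and 69.6. At D10 Mb measured 206, 23.2, 19.0 and 17.5, Hk2 585, 119, 95.9 and 97.1 and Trib3 75.3, 15.6, 12.4 and 14.3. At D11 Nppb measured 1104, 511, 2389 and 548.

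A hypothesis formed after the lists by day were seen was that DNA replication genes change before mitosis genes after both switches. The share of the whole change covered by the DNA replication and the mitosis list was 56.4 ± 3.09% and 36.8 ± 1.91% at D2 and 75.3 ± 10.1% and 65.7 ± 8.22% at D11 (n = 4 each), the days that prompted it. At the other days it was 10.1 ± 0.400% and 9.04 ± 0.462% at D1, 91.7 ± 1.84% and 72.3 ± 1.44% at D3, 10.2 ± 2.67% and 7.00 ± 1.47% at D10, and 90.7 ± 0.977% and 94.2 ± 1.95% at D12. The DNA replication list was ahead in 12 of these 16 libraries and behind in all 4 of D12, so the test, chosen after the values were seen, left the hypothesis open.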
